A study of Mus musculus with 16 samples.

How the data were processed

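RNA was measured by ribodepleted total RNA sequencing in mHiPPoE-2 cells, a transformed neuron line from mouse hippocampus. There were 16 libraries in 8 groups of 2: unedited cells (WT), a METTL3 knockout (METTL3 KO, 1 clonal isolate), 2 Cas9 control clones made without a guide RNA, 2 RBM45 knockout clones (RBM45 KO), and 2 clones of RBM45 knockout cells that carry tagged RBM45 (KO rescue). Libraries were made with a kit that does not mark strand, per the labels' protocols.

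Reads were aligned to the mm10 mouse genome with HISAT2 2.1.0, per the submitters' processing notes, which also name deepTools 3.2.1, Subread 1.6.3, featureCounts 1.6.5, DESeq2 1.32.0, R 3.6.0 and HOMER 4.11.1. The deposited values are raw counts of fragments per feature in 3 tables, written by featureCounts 1.6.3 per the file headers. The gene table counted whole gene bodies, introns included, and the exon table counted exon bins that do not overlap each other, both from a flattened Ensembl 98 annotation of GRCm38, per the file headers. The intron table came from a flattened RefSeq annotation of mm10, per the file headers. A fragment counted for each feature that held at least 0.1 of it, multi-mapping reads were left out, and only fragments of the feature's own strand were counted, per the file headers. With a kit that does not mark strand, that setting leaves uncounted the fragments that happen to read the other strand and gives them to any antisense gene. Reads of a gene and of a gene that overlaps it on the other strand can therefore not be told apart, which concerns 16474 genes of the table. In 1397 rows of the gene table, overlapping genes were joined and are named together with a plus sign.

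Columns were joined to samples by their names. The names of the control columns match no label, and these 4 columns were taken as the controls because all other columns match the other groups. Which control or rescue clone is clone 1 or clone 2 is not settled by the names, so these numbers, and the replicate numbers of those clones, are names only. All per-sample columns were used. Gene symbols, exon numbers and untranslated regions were taken from GENCODE mouse release 21 (GRCm38); symbols matched 53152 of 53333 rows of the gene table and 194263 of 200168 rows of the intron table.

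Gene-table totals ran from 7193908 to 18751324 counts per library, with a median of 12883429. The 12 genes that took at least 0.5% of the counts of any library held 53.3% to 70.6% of the totals, which left 2580543 to 7167022 counts for all other genes. No count fell on any of the 31 mitochondrial genes. Levels are CPM, counts over a library size scaled by TMM (edgeR). Standard deviations (SD) are between libraries, and standard errors (SE) come from the fitted models. P-values measure only the spread between these samples. Counts are of fragments without molecular identifiers, so limits from a count of 0 cover counting error only.

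The unit that received an edit is the clone. The 3 RBM45 comparisons were therefore fitted on the counts of the 2 libraries of each clone added together, with the 6 clones sharing one spread (16867 genes, 3 residual degrees of freedom). METTL3 KO against WT, the control clones against WT, and the clones of 1 genotype against each other were fitted on the 16 libraries in 8 groups (16223 genes, 8 residual degrees of freedom). In these the spread is between replicate libraries, so they compare lines and clones and not genotypes. Both used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with TMM scaling and filterByExpr, and a Benjamini-Hochberg adjusted p under 0.05. Exon and intron bins with a mean of at least 10 counts were tested with diffSpliceDGE of edgeR for a change relative to the rest of their gene, introns together with the exon bins. Lists of genes were tested with camera of limma 3.58.1 with an inter-gene correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and with fry beside it. There were 24 lists, of which the 22 with at least 3 tested members were used. Other software was DESeq2 1.42.0, Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

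The comparisons, their tests, the gene lists, the other settings tried and the rule for named genes were chosen before the data were examined. By that rule Rbm45 and Mettl3 are given first in every group. For RBM45 KO against control, KO rescue against RBM45 KO and METTL3 KO against WT, the 10 largest rises and 10 largest falls are named among genes that pass the test, average at least 2 CPM, and have every library of one side above every library of the other. Predicted genes, Rik clones and pseudogenes by symbol are left out. Where fewer than 5 genes pass, the 5 with the smallest p are named and said not to pass. In lists that pass camera up to 4 members with the smallest p are named, and in each bin comparison the 5 bins of different genes with the smallest p. Genes named outside this rule are said to be chosen after their values were seen.

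The scripts were tested on simulated counts with 200 changed features. With the 6 clones, 9% of genes changed by log2 1 and 78% of genes changed by log2 2 were called, with 8 false calls among 16867 genes. With the 16 libraries and METTL3 KO against WT, 65% and 99% were called, with 4 false calls among 16223 genes. For exon bins, 7% and 48% of 100 changed bins each were called in RBM45 KO against control, with 16 false calls among 144178 bins. In METTL3 KO against WT, 13% and 69% of 100 each were called, with 15 false calls among 105127 bins. In both, false calls were a larger share of the called bins than the adjusted p threshold sets. All called bins other than the changed ones were counted as false. These can include other bins of the changed genes, whose level relative to their gene shifts as well. Whether exon bins called in the data include more false calls than that threshold implies therefore stays open. Because a bin is compared with its own gene, the median estimated sizes of the changed bins were 0.63 and 1.13 in RBM45 KO against control. They were 0.61 and 1.23 in METTL3 KO against WT.

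Other settings chosen at that time were DESeq2 in place of edgeR, DESeq2 size factors within edgeR, no filter and a stricter filter of 10 CPM in 2 clones or libraries, libraries instead of clones as replicates, omission of each clone or library in turn, limma voom with diffSplice, a minimum of 50 counts per bin, a replicate block, fits of only the libraries compared, the correlation of METTL3 KO with RBM45 KO over genes of at least 10 CPM, and restoration with the KO clones split. Settings chosen after seeing the data were exon bins summed per gene, omission of the 12 genes that hold most counts, calls shared by all 4 pairs of clones, all 28 pairs of groups for genes and introns, omission of each library for the bins of METTL3 KO against WT, and, for gene lists, omission of each WT library and each RBM45 KO clone taken alone in the 16-library fit.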

Results

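The data describe gene, exon and intron expression in a mouse hippocampal neuron line after loss and restoration of RBM45, an RNA-binding protein, and after loss of METTL3, the enzyme that writes N6-methyladenosine (m6A) into RNA. Each of the 8 groups had 2 libraries. Gene-table totals were 7193908 to 18751324 counts, and 21116 to 24156 genes had counts. Replicate libraries of a group correlated across genes with r from 0.979 to 0.993, and the variance between replicates was 2.50 to 12.8 times that of counting alone. Between 30.6% and 49.9% of fragments were unmapped. A few transcripts took much of each library: a joined row of ribosomal repeats (CT010467.1+AY036118) held 22.2% of counts on average, Gm42418 held 14.2% and Gm23935 held 6.04%. The 12 top genes held 66.5% of counts in WT, 55.2% in METTL3 KO, 64.9% in the controls, 67.1% in RBM45 KO and 56.3% in KO rescue on average.

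Rbm45 (chromosome 2, 76369984 to 76383768, GRCm38) stood at 14.7 ± 1.90 CPM (counts scaled by library size) in the controls, 8.04 ± 2.08 in RBM45 KO and 23.2 ± 2.05 in KO rescue (SD, n = 4 libraries each), and at 12.6 ± 2.19 in WT and 10.7 ± 0.237 in METTL3 KO (SD, n = 2 each). The highest RBM45 KO library, at 10.8 CPM, lay below the lowest control library, at 12.8 CPM. At clone level the log2 change was -0.88 (SE 0.20) from control to KO and 1.53 (SE 0.20) from KO to rescue, and neither passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p 0.754 and 0.662). The transcript was thus still counted in the KO clones, and its level does not show whether protein was made. In the last exon of Rbm45, which holds the 3′ UTR (76383455 to 76383768), CPM was 1.63 ± 0.391 in the controls, 0.802 ± 0.288 in KO and 0.533 ± 0.126 in rescue (SD, n = 4). The rescue clones thus had more Rbm45 over the gene and no more of its 3′ UTR than the KO clones. Mettl3 (chromosome 14, 52294841 to 52305128, with Tox4 on the other strand) fell from 10.2 ± 2.03 CPM in WT to 3.53 ± 0.255 in METTL3 KO (SD, n = 2), a log2 change of -1.53 (SE 0.20, edgeR quasi-likelihood adjusted p 6.81e-05). It stood at 9.30 in the controls, 9.75 in RBM45 KO and 9.94 in KO rescue.

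**Figure D1:**
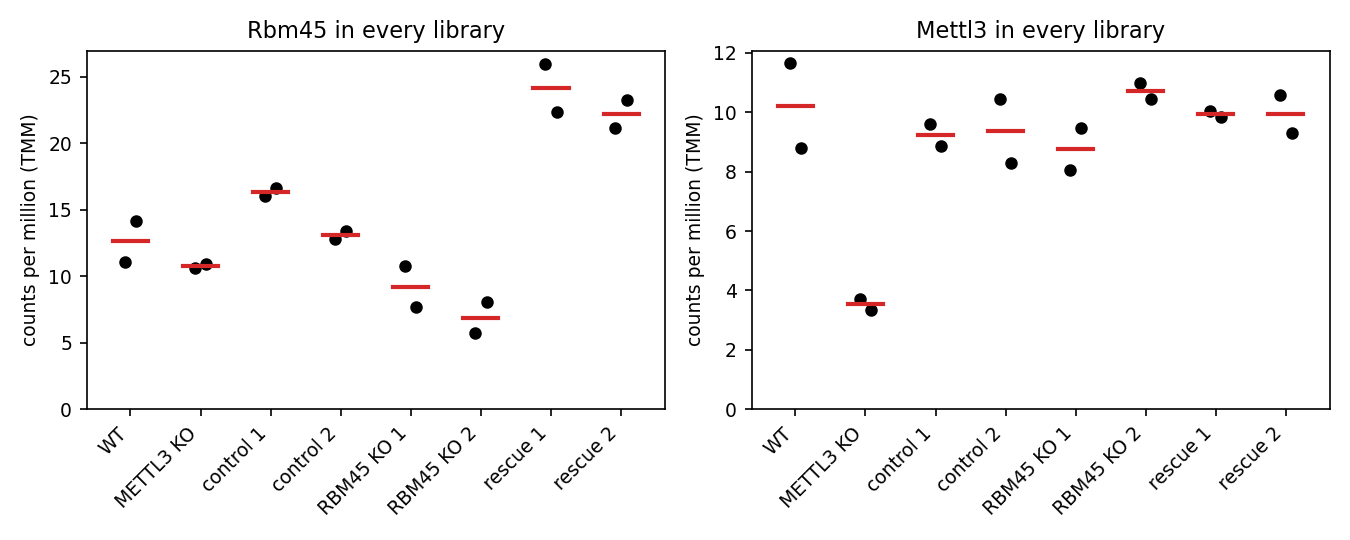
CPM of Rbm45 and Mettl3 in each of the 16 libraries (points) with the mean of each group (bars, n = 2). Rbm45 averaged 8.04 in the 4 RBM45 KO libraries, 14.7 in the 4 controls and 23.2 in the 4 rescue libraries.

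The control and RBM45 KO clones did not group by genotype. In the 16-library fit, edgeR's quasi-likelihood test called 3175 genes between the 2 control clones, 2294 between the 2 RBM45 KO clones and 371 between the 2 rescue clones. In contrast, RBM45 KO clone 1 differed from control clone 1 in 125 genes, and RBM45 KO clone 2 differed from the rescue clones in 224 and 288 genes. RBM45 KO clone 2 differed from the control clones in 2796 and 4135 genes, and RBM45 KO clone 1 differed from control clone 2 in 2982. When the 6 clones were parted into 3 and 3 in every way, 630 genes parted control clones 1 and 2 with KO clone 1 from KO clone 2 with both rescue clones in all 9 pairs, and no other split exceeded 8. The counts moved when single libraries were left out. Between the KO clones they fell to 1472 and 1518 without replicate 1 or 2 of KO clone 1, and to 1353 and 1271 without replicate 1 or 2 of KO clone 2. Between the rescue clones they fell to 191 and 147 without replicate 1 or 2 of rescue clone 1, and to 106 and 173 without replicate 1 or 2 of rescue clone 2. Between the control clones the count was 1750 without replicate 2 of control clone 1.

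**Figure D2:**
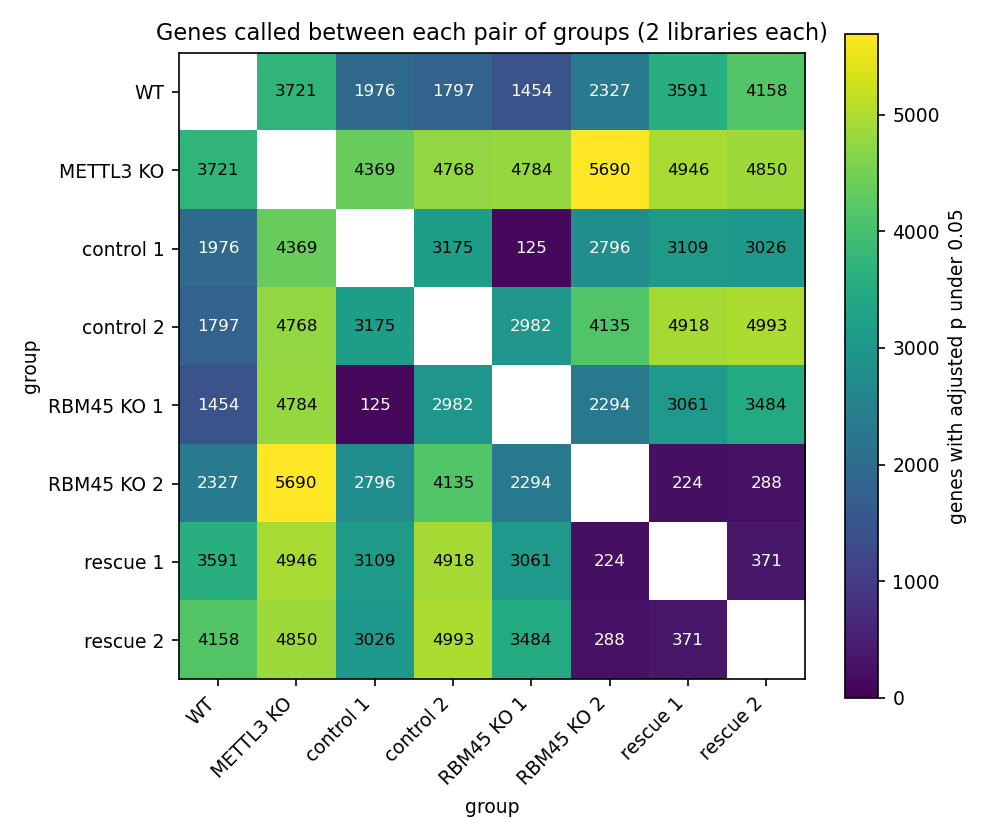
Number of genes called in edgeR's quasi-likelihood test (adjusted p under 0.05) between each pair of the 8 groups, 2 libraries per group. The counts run from 125, between control clone 1 and RBM45 KO clone 1, to 5690, between METTL3 KO and RBM45 KO clone 2.

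RBM45 KO was compared with the Cas9 controls to ask which genes depend on RBM45. Dusp18, a dual-specificity phosphatase, averaged 9.20 ± 1.30 CPM in the controls and 0.379 ± 0.174 in KO (SD, n = 4), a log2 change of -4.57 (SE 0.48). Ide, the gene of insulin-degrading enzyme, averaged 55.9 ± 3.68 and 25.1 ± 3.0, a change of -1.15 (SE 0.15). Med12l averaged 1.21 and 0.242 (-2.38, SE 0.37). Mmp15 averaged 0.716 and 2.44 (1.80, SE 0.29). These are 4 of the 5 genes with the smallest p. None of the 5 passed: with the 2 clones of each genotype as the units, edgeR's quasi-likelihood test called 0 of 16867 genes. The smallest adjusted p was 0.754, while 983 genes had an unadjusted p under 0.05 and DESeq2 called 4. Among them DESeq2 gave Dusp18 an adjusted p of 1.41e-12 and Ide one of 2.92e-05. Leaving out control clone 1 gave 10 edgeR calls and leaving out RBM45 KO clone 1 gave 8. An exact permutation test of 2 clones against 2 cannot give a p below 0.333.

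At the spread between replicate libraries, 17 genes were called in the same direction in all 4 pairs of a KO and a control clone, 8 higher and 9 lower in KO. These genes were chosen after their values were seen. Besides Dusp18 and Ide, the lower ones included Sytl5 (4.65 CPM in controls, 0.150 in KO), the stem cell marker Lgr6 (89.4 and 9.43), Cdh10 (4.62 and 0.518), the substance P receptor gene Tacr1 (23.2 and 7.45) and Ndrg4 (43.6 and 12.7). The higher ones included the cadherin gene Cdh11 (2.99 and 27.1), the histone variant gene H2afy2 (0.446 and 5.17), Ppp1r9a (1.78 and 8.85), the axon survival gene Nmnat2 (2.30 and 7.56) and the antiviral gene Zc3hav1 (5.10 and 12.1). The Y RNA gene Rny1 averaged 9.12 in controls and 21.2 in KO. For 8 of the 17 genes WT lay nearer to KO than to the controls: WT averaged 9.47 CPM for Ppp1r9a, 6.30 for Nmnat2, 15.2 for Zc3hav1, 18.8 for Lgr6, 8.15 for Tacr1, 11.2 for Cdh11 and 2.73 for H2afy2, and the eighth was Ldah. In 9 of the 17 the controls differed from WT the other way than KO from the controls by edgeR's quasi-likelihood test. Parting the same 4 clones by number instead of genotype, clones 1 against clones 2, gave 456 such genes, and the third split gave 25.

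Small non-coding and histone RNAs stood together in this comparison. All 24 tested replication-dependent histone genes were higher in KO, with a median log2 change of 0.46 (camera adjusted p 3.26e-18). Hist1h4c averaged 80.0 CPM against 56.3, Hist2h3b 30.1 against 21.4, Hist1h1b 115 against 81.4 and Hist1h3d 71.8 against 45.3. All 8 tested structural RNA genes were higher as well, with a median of 0.81 (camera adjusted p 1.52e-07), among them Rny1, Rny3 at 33.6 against 15.9, Rnu12 at 9.45 against 5.48 and Snord118 at 1.27 against 0.651. Of 19 interferon-response genes 16 were higher (camera adjusted p 0.00942), among them Ifi44, Ifit3b, Ifit3 and Ifi27 at 4.75 against 2.45. The 16-library fit was also run with 1 KO clone at a time, chosen after the result was seen. There the interferon list passed with neither (camera adjusted p 0.0568 and 0.172), and the histone list with KO clone 1 (5e-07) and not KO clone 2 (0.0521). The axon guidance list, higher in KO, passed camera with each (0.000687 and 0.0011). Both tests use the same control clones, which differed from each other in axon guidance genes, as given below. The controls were themselves lower than WT in interferon genes (camera adjusted p 3.3e-07). With an estimated correlation these lists did not pass, with camera adjusted p of 0.597 for histone and structural RNAs and 0.608 for interferon genes. Adjusted over the list alone, 1 structural RNA gene passed, and no gene of the other lists. The other 19 lists did not pass in the fit of 6 clones, axon guidance (0.0616), m6A readers (0.683) and synapse genes (0.380) included.

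KO rescue was compared with RBM45 KO to ask what returned with tagged RBM45. The 5 genes with the smallest p were Rbm45 itself; the tumour suppressor gene Wwox, at 41.1 ± 4.01 CPM in KO and 79.9 ± 16.4 in rescue (SD, n = 4; log2 change 0.93, SE 0.14); the autophagy gene Atg10 at 5.35 and 12.3 (1.17, SE 0.19); Ube2e2 at 71.6 and 137 (0.91, SE 0.15); and Tmem56 at 55.2 and 27.6 (-1.06, SE 0.17). None passed, and counted over exon bins only, Tmem56 turned to a change of 0.89 (edgeR quasi-likelihood adjusted p 0.884) and the rises shrank to 0.11 for Wwox, 0.58 for Atg10 and 0.37 for Ube2e2. The quasi-likelihood test of edgeR called 0 genes, with 1239 at an unadjusted p under 0.05, and DESeq2 called 42. Leaving out RBM45 KO clone 2 gave 33 edgeR calls. At the spread between replicate libraries, 1219 genes were called the same way in all 4 rescue and control pairs. That count was chosen after the data were seen. Other splits of these 4 clones gave 41 and 29, but so few splits allow no test. RBM45 KO clone 2, which lay near the rescue clones, was itself called against both controls in 1506 genes. With clones as the units, rescue against control likewise gave 0 calls with edgeR and 456 with DESeq2. For edgeR it had 2620 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.276. It gave 13 edgeR calls without control clone 1, 122 without RBM45 KO clone 1 and 105 without RBM45 KO clone 2, clones that enter only through the shared spread.

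Histone and structural RNAs were lower in rescue than in KO, in a contrast that shares the KO clones with the one before, so that some reversal arises by chance. All 24 histone genes were lower than in KO, with a median of -0.51 (camera adjusted p 2.76e-19), and 20 passed edgeR's quasi-likelihood test adjusted over the list alone. Hist1h4c averaged 54.1 CPM against 80.0, Hist1h3b 39.0 against 55.5, Hist1h2bj 26.1 against 39.8 and Hist1h3c 51.3 against 77.6. All 8 structural RNA genes were lower (0.000188), among them Rny1 at 13.2 against 21.2, Rn7sk, Scarna2 and Snord118. With the KO clones split, a test chosen after the result was seen in the 16-library fit, the histone median was 0.51 in KO clone 1 over controls and -0.42 in rescue over KO clone 2 (camera adjusted p 5e-07 and 4.29e-07), and 0.34 and -0.59 in the converse split (0.0521 and 0.00151). For structural RNAs these were 0.50 and -0.53 (0.000687 and 0.000955), and 0.88 and -0.38 (0.0301 and 0.216). The split parts only the KO clones and averages the rescue clones. Both lists were lower in rescue clone 2 than in rescue clone 1 by camera, as given below, so the rescue clones did not fall alike. The make-up of the libraries moved as well: the 12 top genes held 67.1% of counts in KO and 56.3% in rescue, and introns 17.7% and 22.3% of intron and exon reads without those genes. Cholesterol synthesis genes were lower in all 21 cases, with a median of -0.58 (camera adjusted p 4.83e-14): Stard4 averaged 27.0 against 37.6 and Mvk 10.3 against 17.1, with Nsdhl lower too. Mesenchymal and matrix genes were lower (4.94e-05; Snai1, Sparc, Ccn1, Col6a1), as were S-phase genes (0.00182; Mcm3, Fen1, Chaf1b, Mcm5), and interferon genes were higher (0.00214; Mx2, Ifit1 and Usp18, with H2-K1 lower). Against KO clone 1 alone the interferon list did not pass (camera adjusted p 0.180), nor did the S-phase list against KO clone 2 alone (0.0605). With an estimated correlation none of these 6 lists passed, at camera adjusted p from 0.447 to 0.602.

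Against the controls 7 lists passed in rescue, 4 of them (interferon, cholesterol, S-phase and mesenchymal) in the same direction as against KO. Both contrasts share the rescue clones, so some agreement in direction arises by chance. Interferon genes were higher (camera adjusted p 1.1e-05), among them Ifit1 at 1.13 against 0.215 CPM, Ifi44, Ifih1 and Ifit3b. The controls they are set against were lower than WT in these genes, by camera with each WT library left out in turn as well (adjusted p 0.000164 without replicate 1 and 1.31e-11 without replicate 2). Cholesterol synthesis genes were lower (3.74e-07), among them Stard4 at 27.0 against 49.5, Nsdhl and Sqle at 53.6 against 94.5. S-phase genes were lower (0.000542), Mcm3 at 60.3 against 108, Chaf1b, Mcm4 and Fen1. Mesenchymal genes were lower (0.00551; Snai1, Mmp2, Sparc, Ccn1), as were oligodendrocyte genes (0.0368; Mbp, Cspg4, Cnp). Synapse genes were higher (0.0275), among them Cacna1a at 30.9 against 6.82, with Grin2a higher and Syn2 lower, and imprinted genes were higher (0.0124), Peg10 at 299 against 134, Peg3, Zrsr1 and Nnat. None of the 7 passed with an estimated correlation, with camera adjusted p from 0.464 to 0.596.

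Restoration was read from genes that changed 1 way in KO and back in rescue. Of the 17 genes called in all 4 KO and control pairs, 1 was called in the opposite direction in all 4 rescue and KO pairs, against 0.0211 if the calls were independent, and that gene was Ide. The calls are not independent, because the contrasts share the KO clones, and no count for unchanged clones was simulated. Ide stood at 40.3 ± 1.70 CPM in rescue (SD, n = 4), above KO by 0.69 (edgeR quasi-likelihood adjusted p 2.73e-05 between libraries) and below the controls (-0.47). The median share of the KO change reversed over the 17 genes was -15.2%: Dusp18 stood at 0.354 CPM in rescue, Lgr6 at 1.61, Tacr1 at 5.14, Ndrg4 at 8.95, Cdh11 at 40.9 and H2afy2 at 7.99, each as far from the controls as KO or farther. Nmnat2, at 4.42, and Rny1, at 13.2, stood between.

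With the KO clones split between the contrasts, so that no library was shared, KO clone 1 against controls called 62 genes and rescue against KO clone 2 called 58. They shared 4 in opposite directions (Ide, Syndig1, Cdk6 and Gm28294), against 0.102 if independent. Of these, Ide alone changed the same way in KO clone 2 (-1.30 there, -1.02 in KO clone 1): Syndig1 was higher in KO clone 2 than in controls, by 2.37, and Gm28294 (1.28 in clone 1) and Cdk6 (0.64) stood at -0.14 and -0.17 there. They shared 1 gene in the same direction, against 0.119 if independent. The converse split called 1506 and 2274 genes, with 4 in opposite directions (Ide, Rbm45, Cyp39a1 and Fyb2), against 105 if independent, and 787 in the same direction. Each of these 4 was also lower in KO clone 1 than in controls, with log2 changes of -1.02 for Ide and Fyb2, -0.68 for Rbm45 and -0.46 for Cyp39a1. Across genes, which are not independent replicates, the log2 changes of KO over control and rescue over KO correlated with r 0.106 and Spearman coefficient -0.0759 (covariance 0.0410), where unchanged simulated clones gave r -0.516 and covariance -0.105. The 2 splits gave r -0.0602 and 0.660.

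Exon bins were tested for changes relative to the rest of their gene, since RBM45 is studied here as a splicing factor. The clearest change lay in Ide (chromosome 19, 37268743 to 37337852, minus strand). Its bin at 37301663 to 37303649 is 1987 bp long, is annotated as the terminal exon 5 of the non-coding transcript Ide-203, and lies inside intron 11 of the full-length transcript (37298175 to 37303893). The bin averaged 0.553 ± 0.129 CPM in the controls, 7.07 ± 0.941 in KO and 2.33 ± 0.243 in rescue (SD, n = 4), and 0.266 in WT and 0.877 in METTL3 KO. Relative to the gene it rose by log2 3.63 in KO (SE 0.17) and fell by 1.71 from KO to rescue (SE 0.14), with diffSpliceDGE of edgeR giving adjusted p of 6.79e-31 and 1.41e-11. Coding exons before the intron averaged 35.2 CPM in the controls, 16.3 in KO and 22.8 in rescue, and those after it 35.5, 4.45 and 20.5. The ratio of after to before was 1.02 ± 0.104 in the controls, 0.270 ± 0.0560 in KO and 0.897 ± 0.0662 in rescue (SD, n = 4), and 1.17 ± 0.391 in WT and 1.07 ± 0.0148 in METTL3 KO (SD, n = 2).

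**Figure D3:**
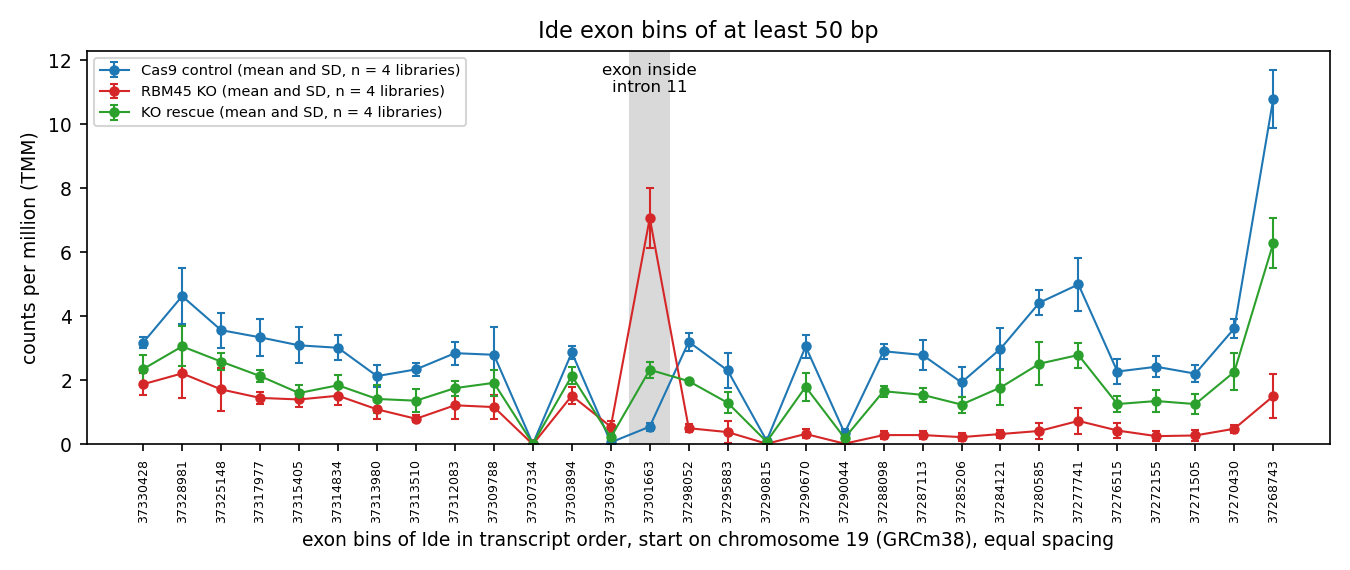
Mean CPM and SD (n = 4 libraries per genotype) of the exon bins of Ide that are at least 50 bp long, in transcript order and evenly spaced. The shaded exon averaged 0.553 in the controls, 7.07 in RBM45 KO and 2.33 in KO rescue, and the bins after it are lowest in RBM45 KO.

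In all, 4 of 140500 exon bins were called in RBM45 KO against control with diffSpliceDGE, 2 higher and 2 lower, with 898 at an unadjusted p under 0.05. The first exon of Nfix-202, a 5′ UTR of this neural transcription factor gene (chromosome 8, 84800141 to 84800344), rose by 1.84 (SE 0.17, adjusted p 0.000159), from 0.264 to 1.89 CPM, and stood at 2.48 in rescue. A coding exon of Tacc2 (chromosome 7, 130621721 to 130626841) changed by -1.61 (SE 0.27, adjusted p 0.00134), from 2.69 to 0.567 CPM, with 0.554 in rescue. A 30 bp coding bin of Hmgn1 (chromosome 16, 96127432 to 96127461) changed by -1.85 (SE 0.26, adjusted p 0.000740), with 8.51 ± 7.54 CPM in the controls (SD, n = 4), 1.15 in KO and 3.44 in rescue. Rsrc1 followed without passing (-1.58, adjusted p 0.136). The Ide call held whichever clone was left out. The Nfix call was lost without control clone 1 (adjusted p 0.465) or KO clone 2 (0.317), the Tacc2 call without control clone 2 (0.384), KO clone 1 (0.299) or KO clone 2 (1), and the Hmgn1 call without KO clone 1 (0.433) or KO clone 2 (1) and under limma diffSplice (0.0573). The count was 2 without KO clone 1 and 1 without KO clone 2. Rescue against KO gave 1 call, Ide, with 1152 bins at an unadjusted p under 0.05; Rbm45, Nap1l1, Anxa6 and Snrnp70 followed without passing. It gave 3 calls without KO clone 2.

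Introns gave a list that partly repeats the exon bins, because some introns hold the same reads. Of 44372 introns, 3 were called in KO against control with diffSpliceDGE, with 1028 at an unadjusted p under 0.05: intron 11 of Ide (3.27, adjusted p 6.88e-29), an intron of the imprinted gene Gnas (chromosome 2, 174300526 to 174327941; 1.94, adjusted p 5.63e-05), and the Tacc2 region already given as an exon (-1.60, adjusted p 0.000236). The Ide intron holds the exon bin, which made up 7.07 of its 7.76 CPM in KO, so its calls here and in rescue repeat those of the bin. The Gnas intron averaged 0.186 CPM in the controls, 2.02 in KO and 2.00 in rescue, also holds first exons of other Gnas transcripts, and was not called without control clone 2 (adjusted p 0.126). Tarbp1 and Cpsf6 followed with adjusted p of 1. The count was 6 without control clone 1 and 1 without control clone 2. Rescue against KO gave 8 introns, with 3261 at an unadjusted p under 0.05. The Ide intron fell by 1.48 (adjusted p 8.5e-08; 0.387 without rescue clone 2), and introns of Cdk8, one of the 12 top genes (1.14, adjusted p 0.00177), Gphn (1.10, 0.0183), Peak1 (0.99, 0.0452) and the joined row Nup188+Lrrc8a+Phyhd1+Gm28035+Gm28038 (1.23, 0.0357) rose. This count was 26 without control clone 1 or control clone 2, 1 without KO clone 1, 5 without KO clone 2, 2 without rescue clone 1 and 0 without rescue clone 2.

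METTL3 KO was compared with WT to ask what changes with loss of the m6A writer; it was 1 clone against the unedited line. Pax2, a homeobox-family transcription factor gene, rose from 0.172 ± 0.0395 to 7.59 ± 2.46 CPM (SD, n = 2; log2 change 5.38, SE 0.54, adjusted p 7.88e-06), Col3a1+Gm47302 from 0.943 to 25.5 (4.58), the neuronal transcription factor gene Bcl11b from 0.438 to 9.62 (4.51) and Mmp2 from 0.610 to 10.3 (4.06). Adam23 (4.57), Zbtb16 (4.33), Svop (4.14), Dact1 (from 0.294 to 4.87 CPM), Megf6 (3.90) and Nexmif (3.86) completed the 10 largest rises. Among falls, the smooth muscle gene Cnn1 went from 10.5 ± 2.58 to 0.377 ± 0.103 CPM (SD, n = 2; -4.86, SE 0.34, adjusted p 1.52e-07) and the surface glycoprotein gene Thy1 from 6.35 to 0.209 (-4.71). Cdh10 (-4.92), Plau (-4.34), Lrch2 (-4.14), Ryr3 (-3.83), Odaph (-3.58) and Col4a6 (-3.44) also fell. Areg (-3.55) and Fosb (-3.47) fell mainly against WT replicate 1: WT averaged 13.5 ± 16.4 and 7.14 ± 7.41 CPM (SD, n = 2), and without that library the changes were -0.80 and -1.66 with adjusted p of 0.375 and 0.122. Thy1 also differed between the RBM45 KO clones, as given below. In the same fit, edgeR's quasi-likelihood test called 3591 and 4158 genes for rescue clones 1 and 2 against WT. Between the 2 control clones there were 3175, and for control clones 1 and 2 against WT 1976 and 1797. The number called for METTL3 KO can therefore not be told from differences between lines. For METTL3 KO against WT, the quasi-likelihood test of edgeR called 3721 of 16223 genes, 1814 higher and 1907 lower. It called 1982 without WT replicate 1, 2024 without METTL3 KO replicate 1 and 1747 without METTL3 KO replicate 2.

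**Figure D4:**
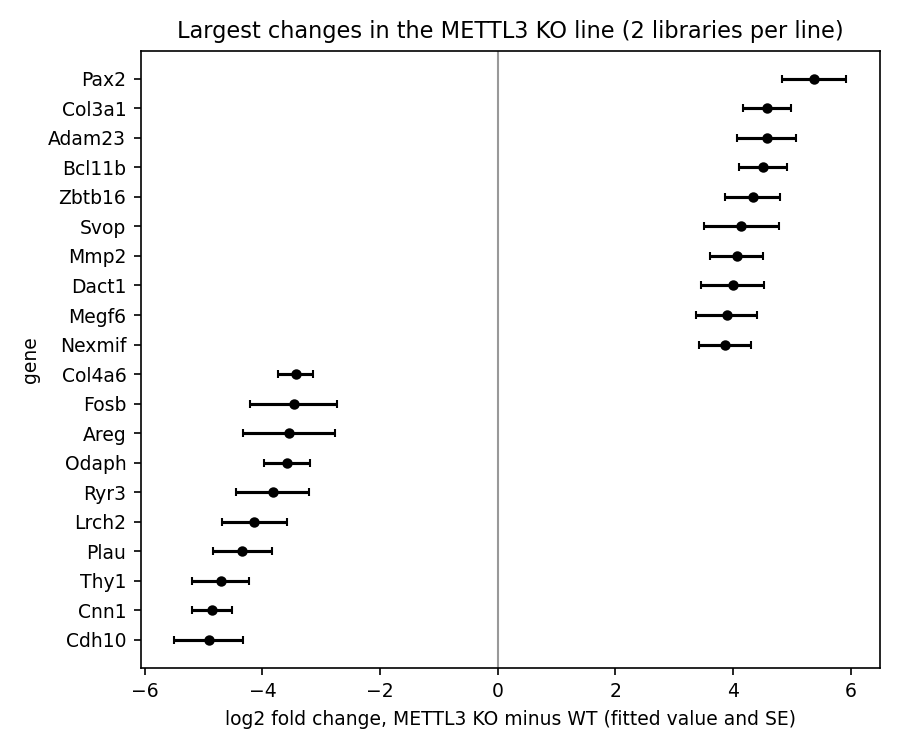
Log2 fold change (fitted value and SE) of METTL3 KO over WT for the 10 largest rises and 10 largest falls among the named genes, 2 libraries per line. Values run from -4.92 in Cdh10 to 5.38 in Pax2.

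Genes of the p53 pathway rose as a list in METTL3 KO (camera adjusted p 0.000263): 17 of 29 were called, 12 of them higher, among them Ccng1 at 73.3 against 26.9 CPM, Trp53inp1 at 42.9 against 11.1, Eda2r at 26.0 against 4.10 and Mdm2 at 76.6 against 31.4. Immediate-early genes fell (1.48e-07), with 21 of 30 called and all 21 lower, among them Dusp5 at 6.20 against 26.9, Etv5, Dusp1 and Fosl1. Cholesterol synthesis genes fell (4.72e-06), with 10 of 21 called, all lower, among them Sqle at 48.5 against 92.1, Cyp51 and Lss. Genes of the integrated stress response fell (1.36e-05), with 12 of 27 called, all lower, among them Nupr1 at 9.72 against 34.2, Ppp1r15a, Mthfd2 and Creld2. The immediate-early and stress lists were also lower in the Cas9 controls than in the same 2 WT libraries, so a high level in WT replicate 1 enters both comparisons. Without that library, a test chosen after the result was seen, METTL3 KO had a median of -0.35 for immediate-early genes (camera adjusted p 0.00113) and -0.17 for stress genes (0.155), and S-phase genes (0.155) did not pass either. Without WT replicate 2 instead, p53 targets (0.0622), splicing regulators (0.273) and G2/M genes (0.315) did not pass camera. G2/M genes fell (0.0109; 11 of 31 called, 10 lower), Cdc20 at 23.0 against 49.2, Cdk1 and Kif2c, with Ckap2 higher, as did S-phase genes (0.0388; 9 of 29 called, 6 lower), Mcm2 at 63.2 against 112, Pcna, Uhrf1 and Rpa2. Replication-dependent histone genes fell (0.000237), with Hist1h4d and Hist1h1a called, while the share of the 12 top genes fell from 66.5% of counts to 55.2% and that of introns without them rose from 17.4% to 23.8%. Splicing regulators fell (0.0288), with 10 of 38 called, 8 lower, among them Ptbp1 at 92.3 against 161, Hnrnpl at 88.8 against 144, U2af1 and Elavl2. With an estimated correlation none of the 8 passed, with camera adjusted p of 0.506 to 0.617. Counted by the quasi-likelihood test and adjusted over the list alone, the calls were 18 for p53 targets, 22 for immediate-early, 12 for cholesterol, 15 for stress, 15 for G2/M, 13 for S-phase, 10 for splicing and 2 for histone genes.

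The m6A machinery moved little as a list (camera adjusted p 0.356). Besides Mettl3, the demethylase gene Fto rose from 64.2 to 101 CPM (0.65), Cbll1 from 8.06 to 13.5 (0.73) and Zc3h13 from 23.5 to 32.5 (0.46). Among m6A readers (0.730) Igf2bp3 rose from 5.58 to 15.4 CPM (1.43) and Igf2bp2 from 26.5 to 51.5 (0.96), and Prrc2a (-0.68) and Fxr2 (-0.53) fell. Besides Mettl3, these 7 genes passed edgeR's quasi-likelihood test over all genes, as did 3721 of 16223 in all. They were chosen after their values were seen. The counts include introns, which were higher in METTL3 KO in general, with a median of 0.24 relative to their genes. Whether these 7 changes hold over exons alone was not tested. The other 12 lists did not pass, with camera adjusted p from 0.0737 for synapse genes and 0.0769 for axon guidance and astrocyte genes to 0.682 for neuronal differentiation, 0.725 for oligodendrocyte and 0.730 for mesenchymal genes.

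In METTL3 KO against WT, diffSpliceDGE called 14 of 101929 exon bins, 13 higher, with 2910 at an unadjusted p under 0.05. The same fit called 25 exon bins between the 2 control clones, 15 higher and 10 lower in clone 2. Control clones 1 and 2 against WT gave 1 each. A number of this size is therefore not particular to METTL3 KO. A long coding exon of Rtn4, the gene of the neurite outgrowth inhibitor Nogo (chromosome 11, 29706410 to 29708770), rose from 21.3 to 45.4 CPM (0.78 relative to the gene, SE 0.10, adjusted p 5.21e-05). A 3′ UTR bin of Rpl22 (chromosome 4, 152332481 to 152334070) changed by 1.08 (SE 0.17, adjusted p 0.000283), a terminal bin of Nsd2 (chromosome 5, 33868879 to 33871406) by 0.99 (0.0033), a bin of Myl6 (chromosome 10, 128491720 to 128491764) by 0.80 (0.0033) and a 3′ UTR bin of Txnl1 (chromosome 18, 63661094 to 63663366) by 1.06 (0.00426). Of the 13 bins called higher, 7 lay wholly in a 3′ UTR, against 6880 of the other 101916 tested bins (6.75%; two-sided Fisher's exact p 7.64e-06). The count depended on single libraries: it was 1 without WT replicate 1, 3 without WT replicate 2, 4 without METTL3 KO replicate 1 and 1 without METTL3 KO replicate 2. Over these 4 fits the Rtn4 bin lost its call once (without WT replicate 1, adjusted p 0.295), the Rpl22 bin without either replicate 2 (WT 0.140, METTL3 KO 0.0579), and the Nsd2, Myl6 and Txnl1 bins in all 4.

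More introns were called, and nearly all were higher in METTL3 KO: 162 of 166, out of 24740 tested with diffSpliceDGE, with 4565 at an unadjusted p under 0.05. Introns of the GTPase-activating protein gene Arhgap21 (1.10 relative to the gene, SE 0.16, adjusted p 1.51e-06), Cdk8 (1.20), Mir3076+Tkt (1.04), Gphn (1.27) and the chromatin gene Jarid2 (1.20) had the smallest p. The median over all tested introns was 0.24, with 77.1% above 0. The introns called higher had a median length of 12100 bp against 5697 bp for all tested, and a median mean count of 64.4 against 20.8. Here too single libraries mattered: the count was 6 without WT replicate 1, 74 without WT replicate 2, 46 without METTL3 KO replicate 1 and 3 without METTL3 KO replicate 2. Among the other 7 groups, in pairs chosen after the result was seen, most introns called in 1 direction were 158, higher in rescue clone 2 than in RBM45 KO clone 2, and 155 were higher in rescue clone 2 than in WT. Of the 5 named introns only that of Arhgap21 kept its call in these 4 fits. Gphn was not called under limma diffSplice (adjusted p 0.124), nor without WT replicate 1 (0.135) or METTL3 KO replicate 2 (0.0990). Intron reads made up 21.9 ± 0.428% of intron and exon reads in METTL3 KO and 19.1 ± 0.663% in WT (SD, n = 2), and 19.3 ± 0.873% in the controls, 18.2 ± 1.43% in RBM45 KO and 20.5 ± 1.47% in rescue (SD, n = 4).

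METTL3 KO and RBM45 KO were set side by side because RBM45 binds m6A-bearing RNA; the 2 comparisons share no library. Across 15905 genes, which are not independent replicates, their log2 changes correlated with r -0.0959 and Spearman coefficient -0.163, and over 7576 genes of at least 10 CPM with r -0.154 and Spearman coefficient -0.235. Of the 9 genes lower in all 4 KO and control pairs, 5 were among the 1907 lower in METTL3 KO, against 1.06 if independent (two-sided Fisher's exact p 0.00187). Of the 8 higher ones 3 were among the 1814 higher in METTL3 KO, against 0.895 (two-sided Fisher's exact p 0.0508). These genes were chosen as differing between clones, and genes that vary between lines may overlap above independence without a shared effect. No other pair of lines was set beside this overlap, so it does not show a shared effect of METTL3 and RBM45.

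The Cas9 controls were compared with WT to see what Cas9 and cloning without a guide RNA bring. Their libraries also differed in unmapped fragments, at 41.6% and 49.9% in WT and 31.0% to 35.7% in the controls, with METTL3 KO at 41.9% and 46.5%. Whether such a difference between libraries enters the results below was not tested. Of 20 interferon genes 8 were called, all lower (camera adjusted p 3.3e-07), among them H2-K1 at 12.1 against 44.3 CPM, H2-D1 at 23.9 against 63.4, Cxcl10 and Ifi27. Immediate-early genes were lower (2.4e-06), with 10 of 30 called, Ier3 at 13.6 against 83.9, Dusp1, Fosl1 and Fosl2, as were stress genes (7.75e-06), with 9 of 27 called, Slc7a11 at 13.3 against 52.7, Ppp1r15a, Cebpb and Slc3a2. These 2 lists stood apart in WT replicate 1: without it, a test chosen after the result was seen, their medians were -0.04 and -0.05 and neither passed (camera adjusted p 0.364 and 0.834). The p53 targets (0.000126) included Cdkn1a at 5.78 against 18.3, Ccnd1, Bbc3 and Trp53inp1, and hypoxia genes (0.000219) included Ndrg1 at 29.8 against 86.5, Ddit4, Ldha and Hk2, and without WT replicate 1 they had adjusted p of 0.0158 and 0.211 by camera. Neural progenitor genes (0.00815; Prom1 at 0.0756 against 6.51) and astrocyte genes (0.0374; Sox9) were lower, and G2/M genes (0.00619; Anln) and oligodendrocyte genes (0.0119; Cspg4 at 95.3 against 44.8) were higher. Without WT replicate 1, G2/M (camera adjusted p 0.257) and astrocyte genes (0.299) did not pass. Without WT replicate 2, progenitor (0.209), oligodendrocyte (0.142) and astrocyte genes (0.0775) did not. With an estimated correlation none of the 9 passed (camera adjusted p 0.201 to 0.473). Counted by the quasi-likelihood test and adjusted over the list alone, 11 interferon, 19 immediate-early, 12 stress, 18 p53, 13 hypoxia, 6 progenitor, 3 astrocyte, 1 G2/M and 1 oligodendrocyte gene passed. The quasi-likelihood test of edgeR called 1458 genes, 518 higher and 940 lower. It called 435 without WT replicate 1 and 959 without replicate 2 of control clone 1.

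Lists of genes also differed between clones of 1 genotype. Axon guidance genes were lower in control clone 2 than in control clone 1 (22 of 32 called, 16 lower), with Sema6a at 2.85 against 27.9 CPM and Sema5a at 3.15 against 16.9. Neuronal differentiation genes were lower (5 of 11 called, all lower), with Uchl1 at 7.27 against 19.7, cholesterol genes were lower (11 of 21 called, 9 lower), with Hsd17b7 at 26.9 against 54.6, and p53 targets were higher (8 of 29 called, all higher), with Eda2r at 4.32 against 0.391. These 4 lists had a camera adjusted p of 0.0235 each, and interferon genes, lower in clone 2 with Bst2 at 1.71 against 6.88, one of 0.0428. Mesenchymal genes were lower in RBM45 KO clone 2 than in clone 1 (camera adjusted p 3.07e-05), with Col1a1 at 77.1 against 1400 and Col5a2 at 151 against 466, while Thy1 was higher at 8.52 against 0.151. Cholesterol genes were lower too (0.00173), with Hsd17b7 at 19.3 against 57.6. In rescue clone 2, immediate-early genes were lower than in clone 1 (0.0124), with Egr3 at 1.80 against 9.49 and Egr1 at 21.5 against 53.2. Structural RNAs (0.0124; Rny3 at 17.5 against 36.8) and histone genes (0.0274) were lower there and cholesterol genes higher (0.0420). With an estimated correlation none of these 11 lists passed: the camera adjusted p was 0.236 for axon guidance and neuronal differentiation, and 0.309 to 0.931 for the others. Counted by edgeR's quasi-likelihood test and adjusted over the list alone, the largest numbers among the lists that passed camera were 23 axon guidance genes between the control clones and 23 mesenchymal genes between the KO clones.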

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

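Of the tests weighed here, those on the relation between clones and on the split of 4 clones were chosen only after the result was seen.

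Among 99 groups of 4 libraries, 3 held a library far from the others. The limit used flags about 1 in 20 groups of 4 independent values. These groups hold 2 clones of 2 libraries each and reuse the same libraries, so that rate does not apply here. Tmem56 stood at 36.8 CPM in control clone 1 replicate 2, where the other controls stood at 52.6 to 53.8. It stood at 38.8 in rescue clone 1 replicate 2, where the other rescue libraries stood at 23.0 to 24.9. Gspt2 had 1 count, 0.0839 CPM, in RBM45 KO clone 2 replicate 1 and 0 in the other 3 KO libraries. No explanation was tested for these values.

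The 2 RBM45 KO clones differed from the controls in opposite directions in 5 genes. The log2 changes for KO clone 1 and KO clone 2 were 0.86 and -2.98 for Olfml2b, -1.45 and 2.37 for Syndig1, -2.24 and 1.57 for Bend4, -1.91 and 1.78 for Xylt1, and 2.42 and -4.37 for Thsd4. The difference between the clones passed edgeR's quasi-likelihood test in each, with adjusted p from 1.41e-09 to 5.08e-07. Of the other genes, 17 were called against the controls in the same direction in both KO clones.

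The clones did not group by genotype: KO clone 1 lay near control clone 1, and KO clone 2 near the rescue clones. A swap of KO clone 2 with an unedited clone is argued against by Rbm45, at 8.04 CPM in its higher library and 10.6 in the lowest control, WT or METTL3 KO library. The Rbm45 level does not settle this for KO clone 1, whose higher library stood at 10.8. A swap of KO clone 1 with an unedited clone is argued against by an exon bin of Ide, the only 1 that set KO clone 2 apart from WT, METTL3 KO and both rescue clones when bins were chosen without KO clone 1 and the controls. KO clone 1 stood with KO clone 2 in it (1 of 1) and no control clone did: its lower library had 5.92 CPM, and the highest control library 0.696. Of 15 genes chosen in the same way, KO clone 1 stood with KO clone 2 in 2 and the control clones in 2 and 1, so the genes do not tell the lines apart. The few genes that held most counts are argued against as the cause, because without them the control clones still differed in 3181 genes and KO clone 1 and control clone 1 in 127. A candidate explanation is descent, with the rescue clones derived from KO clone 2 or a sister of it, and with differences already present between single cells of the line. The labels do not record descent, so it stays open as a hypothesis and was not tested.

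The 17 genes called in all 4 pairs of KO and control clones have to be set against the 3 splits of these 4 clones. The other splits gave up to 456 genes, so all 3 gave at least 17. Since 3 splits are too few for a share under 0.05, they cannot settle the question. A split with many times the real count points to a structure of the samples other than RBM45.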

How the results depend on the processing

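Exon bins summed per gene, omission of the 12 top genes, calls in all 4 pairs of clones, omission of each library for the bins of METTL3 KO, and for gene lists the omission of a WT library or 1 KO clone, were tests chosen only after the result was seen; all others here were planned. Counts below follow the order RBM45 KO against control, rescue against KO, and rescue against control, where edgeR gave 0, 0 and 0 genes. Where a cause is not given, the cause was not tested.

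Treating the 12 libraries as replicates gave 8, 18 and 2512 genes. The 16-library fit gave 2512, 2919 and 5565, because it measures only the spread between replicate libraries of a clone. DESeq2 gave 4, 42 and 456. DESeq2 size factors within edgeR, no filter, the stricter filter, exon bins summed and omission of the 12 top genes moved no count of genes by over 1.5 times. Control against WT fell from 1458 to 422 genes when only those libraries entered the fit. Restoration went from 0 genes in the clone fit to 4 and 4 with the KO clones split and to 1 with calls in all 4 pairs. If independent, the 2 splits would give 0.102 and 105. The second also gave 787 genes in the same direction, so its 4 are fewer than independence would give. The counts of 4, 4 and 1 come from the 16-library fit, so the unit changed together with the split, and neither was tested alone. The correlation of METTL3 KO with RBM45 KO moved from -0.0959 to -0.154 over genes of at least 10 CPM. With exon bins summed, which leaves out introns, the Tmem56 change in rescue against KO reversed to 0.89, and the rises of Wwox, Atg10 and Ube2e2 shrank from 0.93, 1.17 and 0.91 to 0.11, 0.58 and 0.37.

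Under limma diffSplice, exon bins called went from 4, 1 and 14 (the last for METTL3 KO against WT) to 8, 7 and 26, and introns from 8 to 71 in rescue against KO and from 166 to 410 in METTL3 KO. With 12 libraries as replicates exon bins were 13 and 10, and introns in rescue against KO 70. A minimum of 50 counts left 1 intron in KO against control, with fewer introns tested.

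With an estimated correlation, 0 lists passed camera in each of the 8 comparisons, against 3, 6, 7, 8, 9, 5, 2 and 4. By fry, 0 passed in the 3 RBM45 comparisons and between the rescue clones, and 10 between the KO clones, against 2. Fry does not compare a list with other genes. Without WT replicate 1, 5 lists passed camera in control against WT, against 9, and 6 in METTL3 KO, against 8. In the 16-library fit KO clone 1 alone gave 5 lists against control and KO clone 2 alone gave 3, where the clone fit gave 3, so here too the unit changed with the split.

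Leaving out 1 clone or library gave ranges of 0 to 10 genes for KO against control, 0 to 33 for rescue against KO, 0 to 122 for rescue against control, 1747 to 3304 for METTL3 KO against WT, 435 to 2123 for control against WT, and 1750 to 3003, 1271 to 1518 and 106 to 191 between control, KO and rescue clones. Exon bins ranged over 1 to 6, 1 to 3 and 1 to 4, and introns over 1 to 6, 0 to 26 and 3 to 74, for KO against control, rescue against KO and METTL3 KO. Fewer samples enter these fits, and a lone library is taken to vary like the other groups.

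Of 238 values of named genes in METTL3 KO under the alternatives, 235 kept direction and call and 3 lost the call. In KO against control 79 of 90 did and 11 gained a call; in rescue against KO 66 of 80, with 13 gained and 1 reversed. For named bins the numbers were 68 of 81, 65 of 87 and 35 of 58 in KO against control, rescue against KO and METTL3 KO, with 12, 18 and 23 calls lost.

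Replicate numbers were not taken to pair the samples, since that asked for correlations over 0.1 in every pair of groups: deviations of same-numbered libraries correlated by 0.0599 to 0.265, with 4 of 6 pairs over 0.1. A partial pairing stays open, as replicate 1 had the larger unmapped and top-gene shares in each of these 4 groups. With a replicate block for the numbered libraries, METTL3 KO against WT gave 4021 genes, 3702 of them shared, and KO clone 2 against 1 gave 2447, 2282 shared. No call among the named genes changed. A block for the other comparisons, and one for clone number, were planned and not run, because the control and rescue columns carry no settled numbers.

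Depth limits genes of low level: a count of 0 allows up to 3 counts, which is up to 0.323 CPM in the KO libraries and up to 0.432 in WT.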

Other observations

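Of the tests below, the loss of exons after intron 11 of Ide and the level of its other introns were predicted before their values were seen, and all other tests were chosen only after the result was seen.

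The Ide exon inside intron 11 rose in RBM45 KO and fell again in rescue. A clonal difference unrelated to RBM45 is argued against by the rescue libraries: they resemble KO clone 2 elsewhere, yet the bin's highest ratio to the coding exons before it was 0.112 in rescue and its lowest was 0.442 in KO clone 2. A loss of the other exons alone is argued against by the bin itself, at 5.92 CPM in the lowest KO library and 0.696 in the highest control library. The other introns of Ide did not show the rise predicted from more unspliced RNA: they averaged 4.90 CPM in KO and 9.71 in the controls (SD 1.87 and 2.97, n = 4). That mean cannot decide the question. Introns after intron 11 would fall with an early end too, and the coding exons before it fell from 35.2 CPM in the controls to 16.3 in KO. Intron 11 itself argues against more unspliced RNA over its whole length. Its exon bin spans 1987 of 5719 bp. In the 4 KO libraries the bin held 55 of 59, 92 of 102, 80 of 90 and 102 of 110 counts of the intron. Unspliced RNA would also cover the 3488 bp of the intron outside exon bins. If transcripts ended in the exon inside intron 11, the coding exons after it should fall below those before it in every KO library, and they did: the highest KO ratio was 0.309 and the lowest control ratio 0.931.

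A hypothesis for Ide is therefore that RBM45 may keep transcripts from ending in the terminal exon of intron 11, with 0.309 as the highest ratio of later to earlier exons without it. Tagged RBM45 brought that ratio back to 0.897 on average and the bin down to 2.33 CPM, still above the 0.553 of the controls. Reads across the splice junction, which would show the exon joined to the exons before it, are not in the deposited tables.

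Introns higher in METTL3 KO than in WT go with a shift of introns in general: the median of all tested introns was 0.24, against 0.09 and 0.08 for the control clones over WT. Differences between lines of this cell line meet the same number: rescue clone 2 over RBM45 KO clone 2 gave 158 introns called higher, against 162, so the pattern is not particular to METTL3 KO. The control clones against WT gave at most 2, so not every pair of lines differs in this way. The number called rose with intron length, from 11 in the shortest of 4 length classes to 77 in the longest. Introns called higher also held more counts, with a median mean count of 64.4 against 20.8 for all tested. Counts were not compared between the length classes. The median change was lowest in the shortest class and did not rise further among the longer ones, at 0.14, 0.30, 0.29 and 0.23 in order of length, with 64.7%, 80.5%, 81.6% and 81.7% of introns above 0. Whether more unspliced RNA, slower splicing, genomic DNA in 1 preparation or the composition of the libraries may lie behind the median of 0.24 was not tested, and leaving out METTL3 KO replicate 2 left 3 calls.

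Exon bins called higher in METTL3 KO may be enriched for 3′ UTRs: 7 of 13 against 6.75% of the others (Fisher's exact p 7.64e-06, odds ratio 16.1). Greater counts in 3′ UTR bins are argued against as the cause, since none of 10000 random sets of bins matched in mean count held 7, the most being 6 (p 1e-04, the smallest these draws can give). The draws took bins as independent, while some of the 13 came from the same gene, Nsd2. The 25 exon bins called between the 2 control clones were not examined for 3′ UTRs. Whether the enrichment is particular to METTL3 KO therefore stays open. Over all 6887 tested 3′ UTR bins the median was 0.03 with 57.3% above 0, against a median of -0.01 for the other exon bins. The difference was not tested, so whether 3′ UTRs in general shift by a small amount stays open.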
